A study of Drosophila melanogaster with 9 samples.

How the data were processed

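RNA from the skeletal muscle of adult male *Drosophila melanogaster* was hybridised to Affymetrix Drosophila Genome 2.0 arrays, with 1 array per sample and 1 colour. The 9 arrays fall into 3 groups of 3, which are a control, flies with muscle overexpression of Foxo and flies with muscle overexpression of Mnt. Per the labels, the 3 samples of each group were independent biological replicates. Groups and replicate numbers were taken from the sample titles alone.

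The deposited table holds log2 signals for 18952 probe sets, and the authors made them with RMA, per the submitters' processing notes. RMA corrects the background, makes the distributions of the arrays equal and summarises the probes of a probe set. The version of RMA and the probe set definitions are not given in the sources used here. The deposited log2 values run from 2.62 to 14.83 and none was changed before the tests. Because RMA equalises whole distributions, a change shared by most transcripts cannot be seen in these values. Signals of different probe sets are not comparable as amounts of transcript. No sequencing depth applies to arrays, and the 3 arrays per group limit the precision.

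The 183 Affymetrix control probe sets were left out of the tests. The platform annotation used here gives exactly 1 gene for 13647 probe sets and several genes for 402, and 4720 further probe sets are not listed in it. No gene was named from the last 2 classes. Of the probe sets with 1 gene, 13544 matched a gene of the Release 6 plus ISO1 MT annotation by Entrez identifier, and 0 symbols changed. Each gene was represented by its probe set with the highest mean over the 9 arrays, which gave 11982 genes. That annotation was otherwise used only for older gene names and for which genes neighbour each other.

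Genes were tested on the log2 scale with limma 3.58.1 in R 4.3.3, with lmFit and eBayes and an intensity trend in the variance prior. All 9 arrays entered 1 fit with 6 residual degrees of freedom, so that the 3 groups shared 1 estimate of the spread. The comparisons were Foxo versus control, Mnt versus control and Foxo versus Mnt, the last of which is also the test of the difference between the other 2 effects. Tests were two-sided, and Benjamini-Hochberg adjusted p under 0.05 over the 11982 genes was the threshold. Errors of fold changes are limma's moderated standard errors on the log2 scale, and SDs are over the 3 arrays of a group. With 3 arrays against 3, an exact permutation test cannot give a p under 0.1, and 10% of genes have groups that do not overlap by chance.

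In all, 29 gene lists were tested, covering growth signalling, translation, metabolism, muscle structure, protein turnover, defence and markers of other tissues. The set test was limma's camera with a preset correlation of 0.01 between genes and Benjamini-Hochberg adjustment over the lists of a comparison. It was repeated with the correlation estimated from the data and with fry, which does not compare a list with other genes. Some members of the lists are not named by a probe set of their own in the annotation used, among them Thor, Myc and Mhc, and 678 members were measured. The lists, designs, comparisons, named gene rule and alternative settings were fixed before the data were examined, except those named below as chosen later. The rule named foxo and Mnt in every comparison. It also named up to 8 rises and 8 falls of largest size among genes past the threshold whose groups did not overlap. For each list it named up to 2 rises and 2 falls past the threshold, or else the member with the highest mean signal. Other genes are named after their values were seen.

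The alternative settings fixed beforehand were the replicate number as a block, only the 6 arrays of both groups compared, no intensity trend, array weights, a further quantile normalization, centring each array on its median, 2 filters on dim genes, the mean of all probe sets of a gene, leaving out probe sets ending in _s_at or _x_at, a fold threshold, adjusted p under 0.01, each array left out in turn, every probe set tested, and the other 2 set tests. Chosen after seeing the data were fits with a testis score as covariate, with a testis and an accessory gland score as covariates, and without both arrays of the lowest testis score. The testis score is the mean log2 signal of 11 testis genes of the male reproductive marker list, and the accessory gland score is that of its 10 accessory gland genes.

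The gene test was tested on simulated data with the means and residual SDs of these genes and with 100 genes changed at each of 2 sizes. For Foxo versus control it recovered 79% of the 100 genes changed by 1 on the log2 scale and 93% of the 100 changed by 2. For Mnt versus control it recovered 78% and 88%, and for Foxo versus Mnt 80% and 94%. Its false calls numbered 10 of 182, 9 of 175 and 6 of 180 calls. In each comparison the set test found a simulated shift of -0.5 in the 38 ribosome biogenesis genes, with 0 other lists called. The simulated genes vary independently, unlike those in the arrays. Many of them change at once, which eases the Benjamini-Hochberg threshold, so the shares recovered do not apply where few genes change. Comparisons against shared controls were set beside 100 simulations of unchanged groups, in which genes also vary independently.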

Results

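Transcript levels were measured in the skeletal muscle of male flies of 3 groups, with 3 biological replicates each. Flies of the Foxo group overexpressed Foxo in muscle, a transcription factor that insulin signalling holds out of the nucleus. Flies of the Mnt group overexpressed Mnt, a transcriptional repressor that binds Max and opposes Myc. Signals are RMA values on the log2 scale, and 11982 genes were tested. The median signal of an array lay between 5.70 and 5.95 on the log2 scale.

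The targeted transcripts were examined first, in every array. The Mnt probe set lay at 8.48 ± 0.08 (SD, n = 3) in the controls and at 8.48 ± 0.06 in the Foxo arrays. It lay at 9.85, 11.69 and 11.71 in Mnt replicates 1, 2 and 3, which was 2.6, 9.26 and 9.44 times the control mean. The foxo probe set lay at 9.32 ± 0.24 (SD, n = 3) in the controls and at 9.35 ± 0.16 in the Mnt arrays. It lay at 11.95 in Foxo replicate 1 and 10.22 in Foxo replicate 3, or 6.19 and 1.87 times the control mean. In the array labelled Foxo 2 it lay at 9.52, or 1.15 times the control mean, close to the highest control at 9.50. Each gene has 1 probe set with a single gene here, and whether it detects the transgene's transcript as well as the native one is not given in the sources used here.

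**Figure D1:**
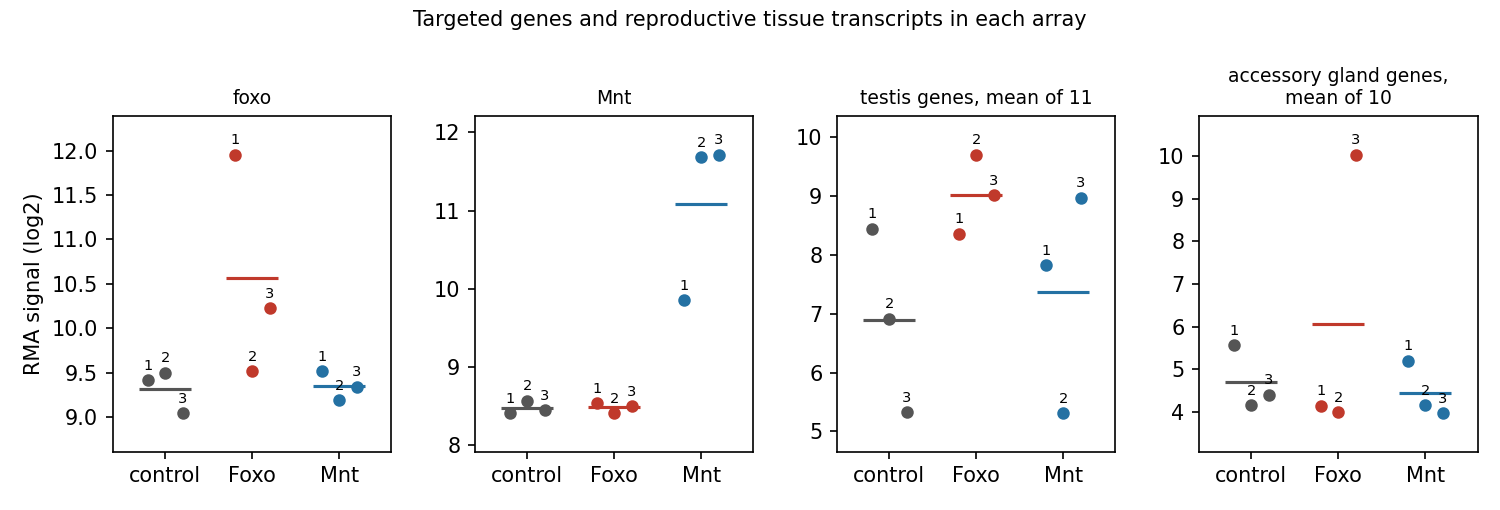
RMA log2 signal of foxo, of Mnt, of the mean of 11 testis genes and of the mean of 10 accessory gland genes, with 1 point per array labelled by its replicate number and a line at each group mean (n = 3). The array labelled Foxo 2 has foxo at 9.52, the Mnt arrays all have Mnt above 9, and Foxo replicate 3 has accessory gland genes at 10.03.

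As groups, neither targeted gene passed the threshold over all genes. The log2 fold change of foxo in Foxo versus control was 1.24 ± 0.52 (SE, n = 3 per group, limma adjusted p = 0.279), and that of Mnt in Mnt versus control was 2.61 ± 0.43 (adjusted p = 0.450). Mnt passed when adjusted over the list alone, among the 7 measured genes of the Myc, Max and Mnt network (adjusted p = 0.00195). Without Mnt replicate 1, the array with the lowest Mnt signal of its group, the log2 fold change of Mnt was 3.22 with an adjusted p of 5.21e-06.

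Transcripts of other male tissues differed between arrays of the same group. The testis score was 6.89 ± 1.56 (SD, n = 3) in the controls, 9.03 ± 0.67 in the Foxo arrays and 7.37 ± 1.87 in the Mnt arrays, and an exact permutation test over 1680 groupings gave p = 0.246. It was lowest in Mnt replicate 2 at 5.31 and control replicate 3 at 5.32, and highest in the array labelled Foxo 2 at 9.70. The accessory gland score was 10.03 in Foxo replicate 3 and between 3.97 and 5.56 in the other arrays. For example, SP, the sex peptide, lay at 11.23 in Foxo replicate 3 and at most at 6.28 elsewhere. The mean of 25 sarcomere genes stayed between 12.37 and 12.82 in all arrays. The first principal component held 61.5% of the variance, and its correlation with the testis score was -0.971. An absolute correlation of at least 0.7 with the testis score across the 9 arrays was found for 2838 genes, or 23.7%.

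Foxo versus control asked which transcripts change when muscle overexpresses Foxo. Cyclin B, a mitotic cyclin, was 4.52 times lower in the Foxo arrays (CycB, log2 fold change -2.18 ± 0.19, SE, n = 3 per group, adjusted p = 0.00862). The piRNA pathway gene squ was 3.25 times higher (1.70 ± 0.14, adjusted p = 0.00862), and the cytochrome P450 gene Cyp4p2 was 2.95 times higher (1.56 ± 0.19, adjusted p = 0.0390). Another cytochrome P450 gene, Cyp4d21, was 2.15 times lower (-1.10 ± 0.14, adjusted p = 0.0478), and lama was 1.84 times lower (-0.88 ± 0.08, adjusted p = 0.00862). The squ signal was low, at 4.56 to 4.70 in the controls, where the lower quartile of all probe sets was 4.27 to 4.31, and both filters on dim genes remove it. All 5 genes separated the 3 Foxo arrays, including the one labelled Foxo 2, from the 3 controls, which the rule that named them required.

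In all, 12 genes passed the threshold, of which 2 rose and 10 fell. The uncharacterised genes CG13794 and CG6664 fell 2.24 and 2.18 times, and CG3764, which neighbours CG6664, fell 1.86 times. With the mean of all its probe sets the log2 fold change of CG3764 went from -0.90 to -0.48 and its call ended (adjusted p = 0.213). Smaller falls were those of CG4461 (1.47 times), of the maltase gene Mal-A5 (1.42 times), of CG5569 (1.40 times) and of CG9399 (1.39 times). Mal-A5 and CG5569 were about as low in the Mnt arrays (log2 fold change against control -0.49 and -0.50). Of the 11982 genes, 2136 had an unadjusted p under 0.05, against 599.1 by chance, and 23.6% had groups that did not overlap, against 10% by chance. This excess cannot be assigned to Foxo alone. The testis score was higher in the Foxo arrays on average, and 2838 genes (23.7%) had an absolute correlation of at least 0.7 with it. These counts are not given with the score in the fit. The adjusted p of CycB became 0.0771 and 0.0646 without control replicates 2 and 3, and those of squ and lama became 0.0771, 0.0552 and 0.0522 without control replicates 2 and 3 and Foxo replicate 1, while the CycB and squ log2 fold changes stayed between -2.39 and -1.97 and between 1.54 and 1.76 in all alternatives that gave a value. Cyp4p2 lost its call without any 1 array but Foxo replicate 3 (adjusted p of 0.0686 to 0.191), and Cyp4d21 without any 1 array but Mnt replicate 2 (0.0649 to 0.266). The count fell to 7, 0 and 0 without control replicates 1, 2 and 3, to 1 without Foxo replicate 1, and to 4, 6 and 5 without Mnt replicates 1, 2 and 3. It was 0 in a fit of these 6 arrays alone, 4 without the intensity trend, 28 with each array centred on its median, 7 with the testis score as a covariate, and 0 without both arrays of the lowest testis score.

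**Figure D2:**
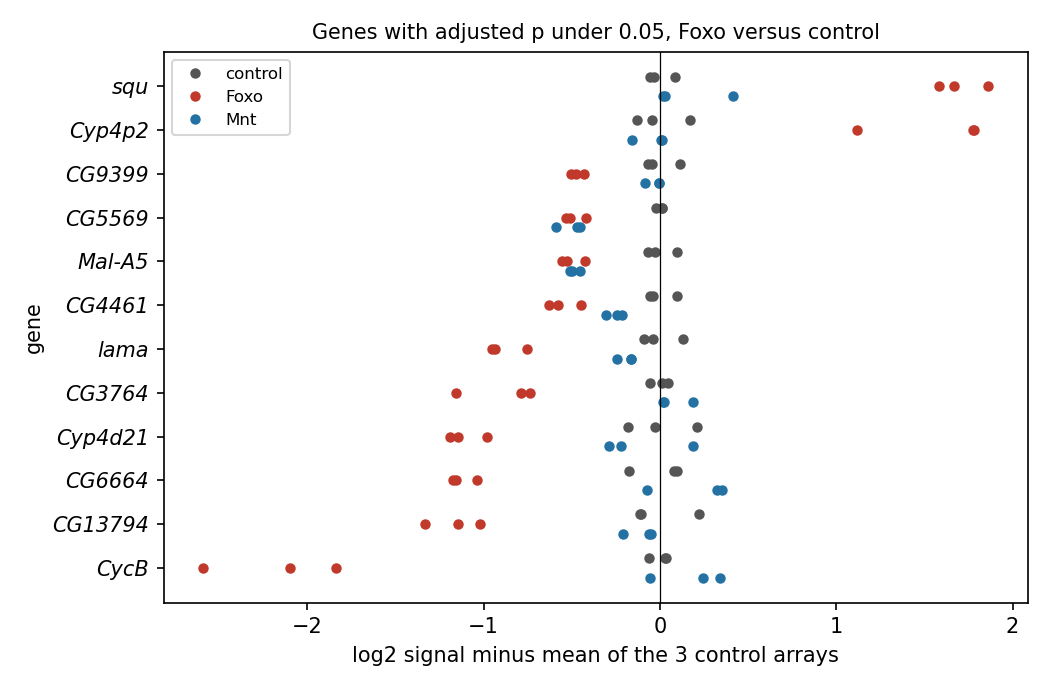
Log2 signal of each array minus the mean of the 3 controls, for the 12 genes past the threshold in Foxo versus control, with 1 point per array in 3 groups of 3. The Foxo points lie apart from the controls for every gene, and the Mnt points lie with the Foxo points for CG5569 and Mal-A5.

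Of the 678 measured list members, limma called 0 over all genes in Foxo versus control, 109 had an unadjusted p under 0.05, and 13 passed when adjusted over the list alone. In the insulin and TOR pathway list, Akt (0.38 ± 0.10), S6k (0.21 ± 0.06) and Sesn (0.40 ± 0.11) passed over the list alone, each with an adjusted p of 0.0399, and the other members of the 15 did not. The log2 fold change of ImpL2, a secreted insulin-binding protein, was -0.74 ± 0.12 (adjusted p = 0.00438 over the secreted factor list alone and 0.116 over all genes). The phagocytic receptor NimC1 of haemocytes had -0.99 ± 0.13 (0.000661 over the haemocyte list alone and 0.0565 over all genes). The complex I subunit gene ND-B8 had -1.24 ± 0.18, and the glycolytic genes Pgi and Pgk had -0.42 ± 0.08 and -0.30 ± 0.09, with adjusted p of 0.00683, 0.00467 and 0.0390 over their lists alone. The others were Strn-Mlck (0.52 ± 0.11), GstT3 (0.45 ± 0.09), GstT2 (-0.33 ± 0.06), the NF-kappaB factor dl (-0.50 ± 0.10) and inaC (-0.38 ± 0.11).

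The list of known FOXO targets did not stand apart. Its 9 measured genes had a median log2 fold change of -0.07, with 2 higher and 7 lower, and a camera adjusted p of 0.912. The median over all genes was -0.06. Sesn, given above, is 1 of the higher 2. Of the 14 genes named in the list, Thor, Ilp6, srl, Myc and Pi3K92E were not measured. Its gene of highest signal, the autophagy gene Atg8a, had -0.03 ± 0.06.

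With the preset correlation, 6 lists were called in Foxo versus control. The male reproductive markers had a median log2 fold change of 1.81 with 20 of 21 genes higher (adjusted p = 3.08e-05), and the gut enzymes had 0.51 with 15 of 16 higher (adjusted p = 0.00107). The proteasome list had 0.08 with 32 of 40 higher (adjusted p = 3.08e-05). Its largest values belonged to variant subunits such as Prosbeta5R1 (0.85 ± 0.43), Rpn12R (0.85 ± 0.31) and Rpt3R (0.81 ± 0.32), and none of these passed. The members Rpt3R, Rpt4R, Prosalpha3T, Prosalpha4T1 and Prosalpha6T are testis genes. Their correlations with the testis score across the arrays were 0.782, 0.646, 0.650, 0.553 and 0.807. The cytosolic ribosomal proteins had 0.02 (adjusted p = 0.0418), where variant genes such as RpL10Aa (1.48 ± 0.60) were largest. The medians of both lists turned negative, at -0.03 and -0.08, when arrays were centred on their medians, a step that moves Foxo against control by 0.10 on the log2 scale. Before this step the median log2 fold change over all genes was -0.06, so small negative medians lie near that of all genes. Haemocyte markers had -0.23 with 9 of 10 lower, and cuticle genes had -0.12 with 80 of 97 lower (both adjusted p = 0.0418). All 6 calls ended with an estimated correlation, where each adjusted p = 0.843, and fry called 0 lists. The other 23 lists had medians between -0.38 and 0.13, and in 4 of them the median and the set test differed in sign. The testis score was higher in the Foxo arrays on average, as given above, beside each of these lists.

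Several of these list calls ended when 1 array was left out or the arrays were scaled again. The male reproductive list had a median of 0.85 and an adjusted p of 0.257 without Foxo replicate 3. The cytosolic ribosomal call ended without control replicates 2 and 3, Foxo replicate 2 and Mnt replicate 3 (adjusted p of 0.137, 0.158, 0.597 and 0.0507), and its median was 0.01 without control replicate 2 or 3, 0.04 without control replicate 1 or Foxo replicate 1, 0.03 without Foxo replicate 3 and -0.02 without Foxo replicate 2. The haemocyte call ended without control replicate 3, Foxo replicate 1 and Mnt replicate 3 (0.0851, 0.186 and 0.0507), and its median was -0.14 without control replicate 3. The cuticle call ended without control replicate 1, Foxo replicates 2 and 3 and Mnt replicate 3 (0.0840, 0.451, 0.360 and 0.0507), and its median was -0.21 without Foxo replicate 1. Centring the arrays ended the cytosolic ribosomal, haemocyte and cuticle calls (0.726, 0.0648 and 0.185; cuticle median -0.22) but not the proteasome call (0.0170), and a further quantile normalization ended the haemocyte and cuticle calls (0.0896 and 0.0749). Without the dimmest 40% of genes the cuticle median was -0.06 and the call ended (0.834). With the testis score as a covariate the camera adjusted p of the cytosolic ribosomal, haemocyte and cuticle lists was 0.848, 0.105 and 0.909. Their medians were then -0.01, -0.09 and -0.02. The proteasome and gut calls were kept in 23 of 25 alternatives each, all but the estimated correlation and fry, although the gut median fell to 0.30 without Foxo replicate 2.

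Mnt versus control asked the same of Mnt. The ribosome biogenesis genes were slightly lower in the Mnt arrays, with 37 of 38 below the control mean and a median log2 fold change of -0.12 (camera adjusted p = 2.06e-10). The call did not hold with an estimated correlation (adjusted p = 0.830) or with fry (adjusted p = 0.698). Examples are RIOK2 (-0.28 ± 0.13), Tsr1 (-0.26 ± 0.07) and bys (-0.21 ± 0.09), none of which passed alone. Rrp1 of this list is a DNA repair nuclease. With the preset correlation the call was kept in the other 23 of 25 alternatives. These do not test the preset of 0.01 itself, while the correlation estimated for this list was 0.332. In Foxo versus control the same list had a median of -0.09 with 34 of 38 lower and was not called (adjusted p = 0.0861), except after a further quantile normalization (median -0.18, adjusted p = 0.0432, range over its alternatives 0.0432 to 0.843). RNA polymerases I and III were also called in Foxo versus control after that normalization (-0.20, adjusted p = 0.0432).

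Single genes did not pass: limma called 0 of 11982 genes in Mnt versus control, while 424 had an unadjusted p under 0.05, against 599.1 by chance, and 8.91% had groups that did not overlap, against 10% by chance. The lowest adjusted p was 0.160, for CG5569 (-0.50 ± 0.06). Mal-A5 had -0.49 ± 0.06 (adjusted p = 0.167), and Tom20, a receptor of mitochondrial import, had -0.30 ± 0.05 (adjusted p = 0.287). Without Mnt replicate 1 the count was 1, which was Mnt itself.

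With the preset correlation, 8 lists were called in Mnt versus control. Besides ribosome biogenesis, lower medians were those of tRNA synthetases (-0.08, 14 of 18 lower, adjusted p = 0.00136), mitochondrial ribosomal proteins (-0.06, 44 of 69 lower, adjusted p = 0.00136) and RNA polymerases I and III (-0.09, 17 of 20 lower, adjusted p = 0.0376). Photoreceptor markers had -0.40 with all 5 lower (adjusted p = 0.00136), where trp, inaC and inaD lay at most at 4.77 in every array and Arr1 and Arr2 were lowest in Mnt replicate 2, at 4.73 and 5.28. Without the dimmest 40% of genes, which leaves only Arr1 and Arr2 of this list, the photoreceptor median was -0.98. Cuticle genes had -0.05 with 63 of 97 lower (adjusted p = 0.0103). Higher medians were those of sarcomere genes (0.09, 19 of 25 higher, adjusted p = 0.00297) and glutathione and redox genes (0.09, 28 of 41 higher, adjusted p = 0.00136). With an estimated correlation none of the 8 was called, the lowest adjusted p being 0.828, and fry called 0. The other 21 lists had medians between -0.23 and 0.17, and in 3 of them the median and the set test differed in sign. Of the 678 list members limma called 0 over all genes, 42 had an unadjusted p under 0.05, and 4 passed when adjusted over the list alone, which were Mnt, Mondo (-0.20 ± 0.06), GstD9 (0.65 ± 0.11) and the peptidoglycan recognition gene PGRP-SB1 (-0.68 ± 0.14). The RNA polymerase call ended without control replicates 2 and 3 and Mnt replicates 2 and 3 (adjusted p of 0.184, 0.122, 0.165 and 0.209), the mitochondrial ribosomal call without control replicate 3 and Mnt replicate 3 (0.0855 and 0.328), the sarcomere call without Mnt replicate 2 (0.211), the glutathione call without control replicate 1 and Mnt replicate 2 (0.109 and 0.0582) and the cuticle call without Mnt replicates 1 and 3 (0.320 and 0.209). With the testis score as a covariate the RNA polymerase and cuticle calls ended (0.0591 and 0.130), and the cuticle median was -0.03. The cuticle call also ended with a further quantile normalization and with centring (0.154 and 0.0665). Without control replicate 3 and without Mnt replicate 3, the medians were -0.06 and -0.05 for RNA polymerases, -0.02 and -0.01 for mitochondrial ribosomal proteins, -0.03 and -0.04 for tRNA synthetases and -0.03 and -0.02 for cuticle genes. The cuticle median was -0.08 without control replicate 1 and -0.13 without Mnt replicate 2. The glutathione median was 0.02 without control replicate 1 and 0.05 without Mnt replicate 2, and that of sarcomere genes was 0.17 without Mnt replicate 1. Centring the arrays moved the medians of sarcomere, glutathione, mitochondrial ribosomal and tRNA synthetase genes to 0.05, 0.05, -0.11 and -0.12, and their calls were kept. The cuticle median turned to 0.04 without the dimmest 40% of genes, where its call ended.

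**Figure D3:**
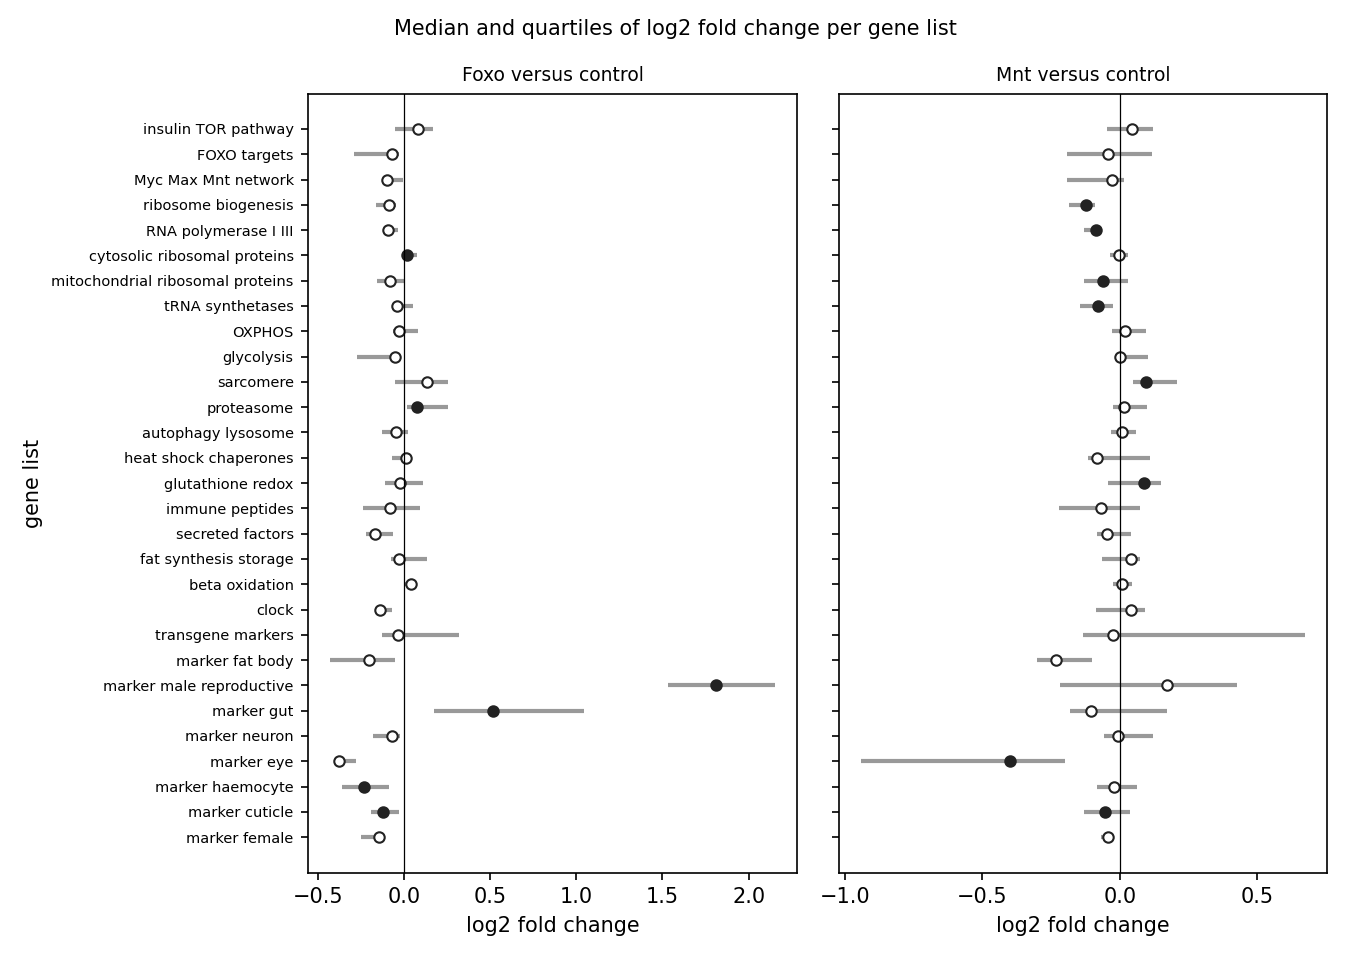
Median log2 fold change (points) and quartiles (bars) of the measured genes of each of the 29 lists, in Foxo versus control and in Mnt versus control. Filled points passed camera with the preset correlation, and the widest shift within each comparison is that of the male reproductive markers in Foxo (1.81) and of the photoreceptor markers in Mnt (-0.40).

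Foxo versus Mnt compared both overexpression groups directly and so tested the difference between their effects. Prx6c, a peroxiredoxin gene, was 6.21 times higher in the Foxo arrays (2.64 ± 0.33, adjusted p = 0.0406), and Cyp4p2 and squ were 3.04 and 2.93 times higher. CycB was 5.11 times lower (-2.35 ± 0.19, SE, n = 3 per group, adjusted p = 0.0141), Arc2 was 2.53 times lower and Corp 2.47 times lower. NimC1 was 2.09 times lower, and deltex (dx), a regulator of Notch signalling, 2.02 times lower. The mitochondrial elongation factor gene mEFTu1 was 1.47 times higher.

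In this comparison 16 genes passed the threshold, with 4 higher and 12 lower in the Foxo arrays, and 7 of them also passed in Foxo versus control. The others that were lower were CG6664, CG13794, CG3764, lama, CG5500, CG6083 and CG32085. With arrays centred on their medians 31 passed, of which 4 were higher and 27 lower, so that the share of higher genes moved by over 10 percentage points. The count fell to 8, 0 and 6 without control replicates 1, 2 and 3, to 1 and 6 without Foxo replicates 1 and 2, and to 2, 2 and 1 without Mnt replicates 1, 2 and 3. It was 0 in a fit of these 6 arrays alone and 0 without both arrays of the lowest testis score. The adjusted p of CycB became 0.0590, 0.0515 and 0.0693 without control replicate 2 and Mnt replicates 1 and 3, and Prx6c lost its call without any 1 array but Foxo replicate 3 (0.0732 to 0.157).

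NimC1 was the 1 list member past the threshold in Foxo versus Mnt. Adjusted over the list alone, 21 genes passed, among them 7 of 41 glutathione and redox genes, all lower in the Foxo arrays, with GstO2 at -0.51 ± 0.11. With the preset correlation 7 lists were called. The male reproductive markers had a median of 1.75 (adjusted p = 9.02e-05), the gut enzymes 0.62 (adjusted p = 9.02e-05), the proteasome list 0.08 (adjusted p = 0.000100) and the cytosolic ribosomal proteins 0.03 (adjusted p = 0.0107). Ribosome biogenesis had 0.03 (adjusted p = 0.0487), neuronal markers -0.13 (adjusted p = 0.0465) and haemocyte markers -0.14 (adjusted p = 0.0487). Centring the arrays turned the medians of the ribosome biogenesis and cytosolic ribosomal lists to -0.03 each. With an estimated correlation each of these ended at an adjusted p = 0.943, and fry called 0 lists. The other 22 lists had medians between -0.14 and 0.05. The male reproductive call ended without Foxo replicate 3 (median 0.76, adjusted p = 0.174), and its median was also 0.76 without Mnt replicate 2. The gut median was 0.31 without Mnt replicate 1 and 0.94 without Mnt replicate 2. The cytosolic ribosomal call ended without Foxo replicate 2 and Mnt replicates 2 and 3 (0.478, 0.0784 and 0.129), where its median turned to -0.02 without Foxo replicate 2 and to -0.00150 without Mnt replicate 3, and it was 0.07 without Foxo replicate 1 or Mnt replicate 1. Other losses were those of the neuronal call without control replicate 3, Foxo replicates 1 and 2 and Mnt replicates 1 and 2 (0.0527, 0.0576, 0.223, 0.109 and 0.0515), with a median of -0.08 without Mnt replicate 1, and of the haemocyte call without Foxo replicate 1 and Mnt replicates 1, 2 and 3 (0.197, 0.0654, 0.0784 and 0.0761), with a median of -0.22 without Foxo replicate 2. The ribosome biogenesis call ended without control replicates 1 and 3, Foxo replicates 2 and 3 and Mnt replicates 2 and 3 (0.0514, 0.0527, 0.0795, 0.122, 0.200 and 0.539), and it was lost in 19 of 25 alternatives. Its median was -0.01 and -0.02 without Foxo replicate 2 and Mnt replicate 3, and 0.06 and 0.10 without Foxo replicate 1 and Mnt replicate 1. A further quantile normalization ended the ribosome biogenesis (median -0.00436), neuronal and haemocyte calls (0.192, 0.0749 and 0.0952), and centring ended these and the cytosolic ribosomal call (0.282, 0.0731, 0.0646 and 0.282) and lowered the proteasome median to 0.02. With the testis score as a covariate the cytosolic ribosomal, neuronal and haemocyte calls ended (0.351, 0.0583 and 0.0991), with medians of 0.01, -0.12 and -0.10, and the ribosome biogenesis median was 0.07.

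The overlap of both effects was 0 genes, since Mnt versus control called none, and independent lists of these sizes would also share 0. Below the threshold, the genes of lowest p in Mnt versus control, CG5569 and Mal-A5, were also called in Foxo versus control. Their log2 fold changes were -0.49 and -0.50 in Foxo and -0.50 and -0.49 in Mnt. These falls against the same controls are thus not particular to the Foxo arrays. Across genes, which are not independent replicates, the fold changes of both comparisons had a correlation of 0.564, where unchanged groups sharing the same controls gave between 0.428 and 0.551 in 100 simulations. The covariance was 0.0488, inside the simulated range from 0.0319 to 0.0492, so that shared controls alone can give a value of this size. The share of genes with the same sign was 64.5%, under the simulated 65.8% to 67.6%. The simulated genes vary independently, unlike those in the arrays, so the simulated ranges are likely too narrow. Whether the correlation or the share departs from chance therefore cannot be told from them. The 3 controls are too few to give each comparison its own set of at least 2 arrays.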

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

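Probe sets outside the gene tests also carried differences between the groups. These are 6787 probe sets that the annotation does not list, that it gives several genes, or that were not the chosen one of their gene. In Foxo versus control 5 of them had an adjusted p under 0.05 when every probe set was tested with limma, with 3 higher and 2 lower. In Foxo versus Mnt there were 8, with 2 higher and 6 lower. The unlisted probe set with the largest rise was 2.15 times higher in Foxo than in control (log2 fold change 1.10 ± 0.11, SE, n = 3 per group, adjusted p = 0.0132), and another unlisted one was 2.72 times lower (-1.44 ± 0.16, adjusted p = 0.0253). A probe set with several genes was 4.21 times lower (-2.07 ± 0.20, adjusted p = 0.0132). No explanation was tested for these.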

How the results depend on the processing

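The fits with tissue scores and the fit without both arrays of the lowest testis score were chosen after the data were seen. Genes changed in Foxo versus control, 12 as reported, numbered 0 with the replicate block, 0 with only the groups compared, 4 without the intensity trend, 28 with arrays centred on their median, 6 without probe sets ending in _s_at or _x_at, 6 with a fold of at least 2, 3 at adjusted p under 0.01, 19 with every probe set, 7 with the testis score, 6 with both tissue scores and 0 without both arrays of the lowest testis score. Foxo versus Mnt, 16 as reported, gave in the same order 1, 0, 5 and 31, then 10 with a fold of at least 2, 0 at adjusted p under 0.01, 27, 6, 7 and 0. Leaving out 1 array gave 0 to 13 genes in Foxo versus control, 0 to 14 in Foxo versus Mnt and 0 to 1 in Mnt versus control, where every other alternative gave 0. The 13 and 14 came without Foxo replicate 3, and they held only 6 of the 12 and 7 of the 16 reported genes. Fewer genes at stricter thresholds, and fewer arrays, follow from those settings, and the cause of the other moves was not tested. Same-numbered arrays did not deviate together, since 1 of 9 such pairs correlated above 0.1 and 2 of 9 arrays correlated best with their own number, so the replicate block removes no known pairing. CycB kept its call in Foxo versus control in 19 of 24 alternatives, squ in 16 of 22, and CG3764 in 5 of 24, and each kept its direction in all of these. The log2 fold change of foxo was never past the threshold. That of Mnt ranged from 2.29 to 3.22 when 1 array was left out and passed only without Mnt replicate 1. It has no value without _s_at probe sets, since its only probe set is of that kind. The ribosome biogenesis median of -0.12 in Mnt versus control lost its call with an estimated correlation and with fry, at the same value of -0.12. It kept the call in the other 23 of 25 alternatives, which all use the preset correlation. In Foxo versus control the haemocyte and cuticle calls were kept in 12 of 25 alternatives each and the cytosolic ribosomal call in 9; in Mnt versus control the cuticle call was kept in 14 and the RNA polymerase call in 13; in Foxo versus Mnt the cytosolic ribosomal, haemocyte, neuronal and ribosome biogenesis calls were kept in 14, 9, 7 and 6. The FOXO target list was called in none. Of the lists not called as reported, 9 were called in at least 1 alternative in Foxo versus control, 10 in Mnt versus control and 9 in Foxo versus Mnt. In Foxo versus control these include the secreted factors in 10 alternatives and the sarcomere genes in 9, the latter with a median of 0.19 and an adjusted p of 9.71e-06 without Foxo replicate 2. The set test of the cuticle list in Foxo versus control changed direction with both tissue scores, while its median stayed negative at -0.00184. Signal over background could not be measured from RMA values, so the limit it sets is open.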

Other observations

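Further transcripts varied between arrays of the same group without following it. The larval serum protein gene Lsp2 lay at 5.84 in control replicate 1, 6.23 in Mnt replicate 1 and 7.56 in the array labelled Foxo 2, and at least at 9.09 in the other arrays. The digestive enzyme gene Jon99Fi lay at 9.15 in control replicate 1 and at 3.39 and 3.51 in control replicates 2 and 3. The yolk protein genes Yp1, Yp2 and Yp3, markers of females, reached at most 4.44, 5.29 and 6.60.

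The tests below were chosen after the result they measure was seen, except the test of other testis genes, the test of random lists matched on level and the counts over splits. The splits of 6 arrays into 3 and 3 number 10, too few for a share under 0.05. For Foxo versus control, 1 of the 10 gave as many genes as the real 12, and the highest of the others gave 0. For Mnt versus control, all 10 gave at least the real 0, and the highest of the others gave 6. For Foxo versus Mnt, 2 of the 10 gave at least the real 16, and the highest of the others gave 129, which is several times the real count and points to a structure of the samples. That split sets Foxo replicate 1 and Mnt replicates 1 and 2 against the rest. Its gap in mean testis score, 2.07, was the widest of those 10, while the splits of widest gap in Foxo versus control and Mnt versus control (2.19 and 2.56) gave 0 genes.

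The testis score, a mean over 11 genes, ranged over 4.39 on the log2 scale between arrays, and over 3.66 within the Mnt group. An array effect on genes of one signal level is argued against, since the widest of 10000 random lists matched on level spanned 0.368 of that range. Array-wide references varied little after RMA: the hybridization controls, the array median and the genes of the same signal levels spanned 0.453, 0.218 and 0.133. Array brightness left in these values is thus argued against as the source of a range of 4.39. With each subtracted, the score kept at least 0.851 of its range, over all arrays and within each group. References this narrow left no room for a large fall. An effect of the normalization itself cannot be judged from values made after it. Testis RNA in some samples may be the source but stays open: 36 other testis genes, 5 of them also in a fixed list, had a median correlation of 0.754 with the score, under the 0.8 set beforehand, while the highest of 10000 random lists reached 0.442. Of the 36, 16 had a correlation over 0.8, and only 11 had a mean signal of at least 6 on the log2 scale. In those 11 the correlations ran from 0.839 (m-cup) to 0.999 (S-Lap7), except 0.690 for mia and 0.259 for bol. The bound of 0.8 was set for the median of all 36, most of which have dimmer signals. Of the 3 with the highest signals, S-Lap7 and Mst77F ranged over 5.44 and 4.78, and bol over 0.62. No biological explanation was tested, since the design names none within a group.

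The foxo signal of the array labelled Foxo 2 was 1.57 below the mean of the other 2 Foxo arrays on the log2 scale. Sarcomere genes were lower there by a median of 0.314, with an upper quartile of 0.555. Dilution of muscle RNA that lowers their signals as much as that of foxo is thus argued against. Their mean lay between 12.37 and 12.82 in the Foxo arrays, near the highest signal of 14.83, where arrays may understate a drop. Among dimmer members, Zasp67 lay at 4.15 in the array labelled Foxo 2, against 6.68 and 5.32 in Foxo replicates 1 and 3. TpnC73F lay at 7.06, against 7.09 and 6.89. A dilution hidden by bright signals stays open. A control or Mnt sample under this label is argued against: in 9 genes called without this array, it showed a median of 0.801 of the shift of the other Foxo arrays (lower quartile 0.743), the highest such median of a control or Mnt array was 0.194, and 6 of the 9 lay beyond all control and Mnt arrays. The exceptions were CG10383 and Pcyt1, which lay near the controls there, and CG5569, at 10.15 there against 9.98 to 10.12 in the Mnt arrays. A lower expression of the transgene in this sample could also give this and was not tested, so every direction drawn for the Foxo group includes 1 array whose foxo probe set signal was not raised.

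The genes that separate all 3 Foxo arrays from the controls were weighed against 3 explanations. The median fold of the 12 genes kept 0.838 of its size with the testis score in the fit. This cannot exclude unequal testis RNA, since calling favours genes of small spread within groups, where the score varied widely. A gene that follows the score would hardly be called, so a kept fold was favoured by the choice of genes. The values show only that the 12 genes follow the score weakly within groups. Only 5 of the 12 stayed called, as the median absolute log2 fold went from 1.0 to 0.84 and the median SE from 0.11 to 0.10. Of those that lost the call, with 1 residual degree of freedom fewer, Cyp4p2 (1.58) and CG4461 (-0.56) had log2 folds that did not shrink. Clusters of neighbouring genes, as stretches of chromosome from different strains could give, were not in excess among the 50 genes of largest absolute t. There 1 pair, CG3764 and CG6664, lay within 5 genes of each other, and 10000 random sets had a median of 1 (permutation p = 0.647). Both genes of this pair are among the 12 and are next to each other among the measured genes. Clusters among the 12 alone were not tested, so for them this explanation stays open. The dose of foxo, as its probe set shows it, stays open: in the 9 genes called without the array labelled Foxo 2, its mean shift was 0.681 of that of the other Foxo arrays, between the bounds of 0.5 and 0.8, where 7 genes shifted by 0.743 to 1.52 and CG10383 and Pcyt1, outside the 12, by -0.0928 and 0.0959. Foxo activity that this probe set does not show, and single-gene differences between the strains, which the groups carry with them, stay open and were not tested.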
